A study of Mus musculus with 4 samples.

How the data were processed

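The samples were 4 mRNA libraries of isolated cortical astrocytes from mice at postnatal day 5, with 2 libraries labelled WT and 2 labelled KO. Per the labels, total RNA was extracted with Trizol and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 were among the tools used, with no roles stated. The notes name the mouse build mm9, but 21269 of the 23475 gene positions in the files (90.6%) were identical to the GENCODE M21 annotation of GRCm38, and coordinates are therefore given on GRCm38. Whether counting used the strand is not given in the sources used here.

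The authors deposited 4 tables, each comparing a library labelled KO with a WT library. Each deposited table holds whole-number counts per gene for its 2 libraries, per the file headers. A second value per library, deposited as a normalized column, equals the count scaled to a common library total (CPM), with 0 replaced by 0.5. The authors' deposited log2 fold change is the log2 ratio of those normalized values. The deposited p-value and adjusted p-value columns come from a test on 2 single libraries that the file headers do not name, and the authors' significant label went with an absolute log2 fold change of at least 1 and a p under 0.05.

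The 4 tables were joined by gene, and counts of 1 library agreed between tables. A gene was listed where both libraries of a pair had a count, or where 1 had 0 and the other at least 5. A count missing from all tables was set to 0, and it can be at most 4. Listed counts per library ranged from 14224519 to 16961160, and unlisted genes held at most 0.0191% of a library's counts. Replicates differed by more than sampling noise, with a chi-square per gene of 20.3 between the KO libraries and 30.7 between the WT libraries, so all 4 counted as separate libraries. Nothing in the labels says whether they came from separate animals, so p-values measure the spread between these libraries. The sex-linked transcripts given below show that the KO libraries came from different animals, and the spread between them includes a sex difference. For the WT libraries, which both carried Xist, the question stays open. Between the groups the chi-square per gene ran from 33.4 to 40.7. By Spearman correlation of CPM, KO replicate 2 lay at 0.946 and 0.939 to WT replicates 1 and 2, and KO replicate 1 at 0.938 and 0.929. The WT libraries correlated with each other at 0.938, no more closely than with KO replicate 2, and the KO libraries at 0.956.

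Groups were compared with edgeR 4.0.16 (TMM normalization, estimateDisp, quasi-likelihood fit and test, R 4.3.3) on genes kept by filterByExpr with a minimum count of 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread left 2 residual degrees of freedom, and the common dispersion was 0.204. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM used TMM-scaled library sizes. The 30 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, over lists with at least 5 tested members. The values of 1 of these lists are not reported here, and it stays in the counts of lists. The rule named Pdcd1 and its ligands; the 10 genes higher and 10 lower with the largest change among those past the threshold, with a mean of at least 1 CPM, no predicted locus and no overlap between groups, filled up by smallest p; and from each list up to 4 members past the threshold or otherwise the 2 most abundant.

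On simulated data with 200 changed genes, edgeR found 25 of 100 genes changed 2-fold and 73 of 100 changed 4-fold, and called 13 unchanged genes, among 16655 genes in the comparison of KO with WT. DESeq2 found 49 and 84 with 61 unchanged genes called, and limma-voom found 34 and 71 with 6. In the list test a simulated list of 24 genes raised 2-fold was called, and 0 of 30 unchanged lists were. Genes were drawn independently there, while the estimated correlation between genes was 0.517 in the microglia list and 0.729 in the endothelial list. The simulation thus does not show that false calls are held down in such lists. Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters, a looser threshold, a replicate block and leaving out each library, and for lists an estimated correlation and fry. With an estimated correlation camera is also held to the residual degrees of freedom, 2 here and 1 without a library. The inflammatory list had an estimated correlation of 0.00411, below the preset 0.01, yet its camera p rose from 7.99e-08 to 0.0301. A list can thus hardly pass that alternative, and its failure is no measure of how its genes correlate. Alternatives added after the data were seen were unlisted counts at their upper limit, no X and Y genes, a robust fit, and lists without genes tracking the microglia list. Near-identical copies were found with BLAST 2.17.0, at 95% identity or more over at least 80% of a transcript of GENCODE M21.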

Results

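Gene expression was measured by mRNA sequencing in astrocytes isolated from the cerebral cortex of mice at postnatal day 5. Astrocytes are glial cells that support synapses and blood vessels, and at this age they are still growing into their mature shape. The libraries fell into 2 groups of 2: WT, from mice carrying a floxed PD-1 gene, and KO, from mice in which the labels describe a conditional PD-1 deletion. The comparison asks what changes in the astrocyte preparation when PD-1 (gene Pdcd1), an inhibitory immune receptor, is deleted. Gene counts summed to 16103987 in KO replicate 1, 16405245 in KO replicate 2, 16961160 in WT replicate 1 and 14224519 in WT replicate 2, and between 19199 and 21583 genes had at least 1 count in a library. KO replicate 2 carried 2472 counts of the Y-linked gene Ddx3y and 0 of Xist, while the other 3 libraries carried 0 counts of Ddx3y and between 6732 and 8564 of Xist. KO replicate 2 thus stood apart in its sex-linked transcripts, and the count of changed genes is also given without it.

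The targeted gene was not detected in the WT libraries, so its counts cannot check the group labels. Pdcd1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553, minus strand, GRCm38) had 20 counts in the library labelled KO 2, or 1.22 CPM (counts scaled to the library size; exact 95% binomial interval 0.745 to 1.88), and 0 counts in both WT libraries. A count of 0 allows up to 0.177 CPM in WT replicate 1 and 0.211 CPM in WT replicate 2. In the library labelled KO 1 Pdcd1 was not listed, which leaves room for at most 4 counts. These intervals and limits cover counting error only. Which exons were deleted is not given in the sources used here, so whether these reads lie outside the deleted part was not tested. The deletion is described as conditional, so the reads may also come from cells that keep the gene, which was not tested either. With 0 counts in both WT libraries there is no level from which a loss could be seen. The groups are called the libraries labelled KO and WT throughout. Pdcd1lg2, which encodes the ligand PD-L2, had 21 counts in the library labelled KO 2, 0 in both WT libraries, and was not listed in the library labelled KO 1. Neither gene passed the low-count filter, so neither was tested. Cd274, which encodes the ligand PD-L1, was measured at 19.7 CPM and 24.9 CPM in the libraries labelled KO and at 5.51 CPM and 8.97 CPM in the WT libraries, a log2 fold change of 1.63 ± 0.38 (SE), and did not pass over all genes (edgeR, adjusted p = 0.35). Ptpn6, a phosphatase that acts downstream of PD-1, had 40.0 ± 0.66 CPM in the libraries labelled KO and 8.27 ± 4.8 CPM in WT (SD, n = 2 each), and also did not pass (adjusted p = 0.26). Ptpn11, a related phosphatase, had a log2 fold change of 0.26 ± 0.16 (SE, adjusted p = 0.77). Adjusted over the list alone, 2 of the 3 tested members of the PD-1 pathway list passed, in libraries in which the microglia list was also higher (median 1.88). With 3 tested members the list was too short for the list test. It had 5 tested members, Pdcd1 and Pdcd1lg2 included, when any library but KO replicate 2 was left out. Those 2 genes had listed counts only in KO replicate 2 and passed the filter through it, so their upward direction was fixed. Without KO replicate 1 it then passed as higher, with a median log2 fold change of 2.25, the value of Ptpn6 (camera, adjusted p = 0.000523, and 0.812 with an estimated correlation). Without WT replicate 1 and without WT replicate 2 it did not pass (adjusted p = 0.06 and 0.0716).

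P2ry12, a purinergic receptor of microglia (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), was 5.89-fold higher in the libraries labelled KO, at 615 ± 76.5 CPM against 104 ± 13 CPM (SD, n = 2 each; log2 fold change 2.56 ± 0.16 SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.029). Tpm3-rs7, a copy of the tropomyosin gene Tpm3 on chromosome 14, rose from 16.8 ± 0.37 CPM to 239 ± 3.6 CPM (log2 fold change 3.83 ± 0.15, adjusted p = 0.0073). Eno1b, a copy of the enolase gene Eno1 on chromosome 18, rose from 0.59 ± 0.25 CPM to 67.9 ± 8.5 CPM (log2 fold change 6.85 ± 0.38, adjusted p = 0.024). The copies were 99.1% and 99.5% identical to their parent genes, so the counting could split reads between copy and parent, and their values are uncertain. These 3 genes, of 17696 tested, were the only ones higher past the threshold, and 0 were lower. At an unadjusted p under 0.05 there were 1040 higher and 427 lower genes. With no gene changed, 885 of the 17696 would fall under that p, in both directions together. Such counts are therefore no count of changed genes. DESeq2 called 315 higher and 63 lower, and limma-voom called 25 higher and 3 lower. Without KO replicate 2 edgeR called 0 genes (613 higher and 408 lower at an unadjusted p under 0.05), without KO replicate 1 it called 6 higher and 1 lower, without WT replicate 1 it called 1 higher, and without WT replicate 2 it called 41 higher and 1 lower.

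The next genes by p did not pass the threshold. Among those higher in both libraries labelled KO were Lyz2, the lysozyme of myeloid cells (log2 fold change 2.37 ± 0.17 SE, adjusted p = 0.051), P2ry13, another purinergic receptor (2.24 ± 0.17, adjusted p = 0.056), the prostaglandin D synthase Hpgds (2.16 ± 0.18, adjusted p = 0.073) and Csf1r, the receptor that microglia need to survive (1.90 ± 0.16, adjusted p = 0.073). Serinc3, the lysosomal protease Ctsb and the chemotactic receptor Gpr183 had log2 fold changes of 1.31, 0.97 and 3.23. Among those lower were Stk25, a kinase of neuronal polarity, at 77.9 ± 15 CPM against 254 ± 5.4 CPM (SD, n = 2 each; log2 fold change -1.70 ± 0.17 SE, adjusted p = 0.099), the RNA-binding protein gene Adarb2 (-1.32 ± 0.14, adjusted p = 0.10) and D2hgdh, a mitochondrial dehydrogenase (-2.97 ± 0.33, adjusted p = 0.10). Hmgn2, Dbi, AC149090.1, Prdx6, Dner and Tuba1a had log2 fold changes of -0.95, -0.98, -1.45, -0.57, -0.65 and -0.36. Phgdh, the first enzyme of serine synthesis, had a log2 fold change of -0.47 ± 0.09, and 2 of its 3 near-identical copies had an unadjusted p under 0.05, so its value is uncertain. Hmgn2 also has a near-identical copy. Stk25 and D2hgdh lie within 3 Mb of Pdcd1, as the map of that region shows.

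**Figure D1:**
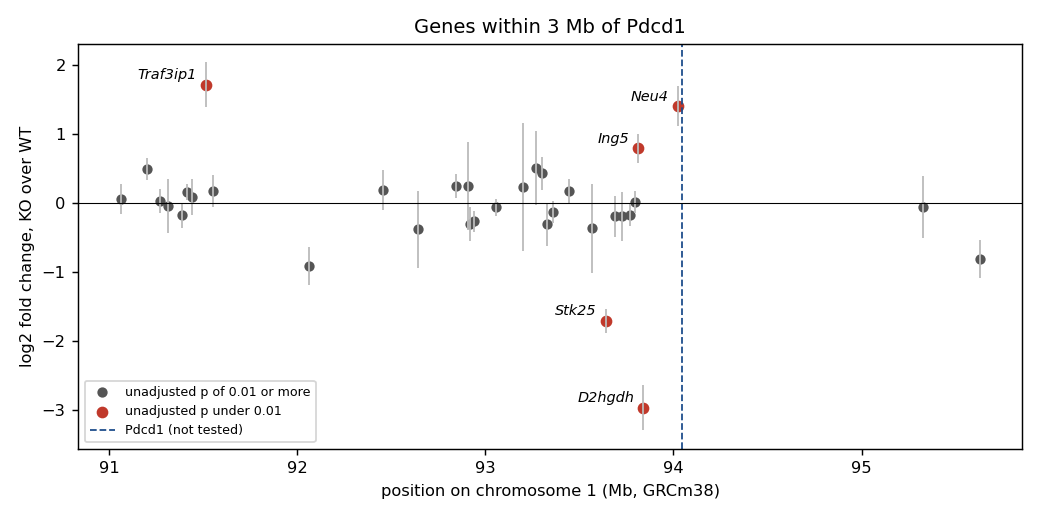
Log2 fold change between the libraries labelled KO and WT (points, with standard errors as bars) against position on chromosome 1 (Mb, GRCm38) for the 34 tested genes within 3 Mb of Pdcd1 with a mean of over 4 CPM. 5 genes had an unadjusted p under 0.01 and are named; D2hgdh and Stk25 were lower, and Neu4, Ing5 and Traf3ip1 were higher.

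Transcripts of microglia were higher as a group in the libraries labelled KO. All 24 members of the microglia and macrophage list had a log2 fold change above 0, and in 23 both libraries labelled KO lay above both WT libraries, where chance separates the groups in either direction for 33.3% of genes and 39.6% of all tested genes were separated. Over all genes 1 member passed, P2ry12, and adjusted over the list alone 22 passed. The median log2 fold change was 1.88, and the list passed the list test (camera, adjusted p = 6.6e-20) with the preset correlation of 0.01 but not with an estimated one (adjusted p = 0.756). The latter, at 2 residual degrees of freedom, has little power. The former assumes nearly independent genes, where the estimated correlation of this list was 0.517, so neither p-value is a sound measure. Csf1r had 1008 ± 189 CPM in the libraries labelled KO and 269 ± 28.4 CPM in WT, and the fractalkine receptor Cx3cr1, chosen after its values were seen, had 737 ± 29.8 CPM and 149 ± 58.1 CPM (SD, n = 2 each). The endothelial list had a median of 1.75 with 18 of 18 members above 0 (adjusted p = 4.1e-07, and adjusted p = 0.756 with an estimated correlation). Of its members 0 passed over all genes and 0 adjusted over the list alone. Its most abundant members, Bsg and the glucose transporter Slc2a1, had log2 fold changes of 0.46 ± 0.15 and 0.59 ± 0.28 (SE), and that of Slc2a1 was 0.16 without KO replicate 1. The pericyte, smooth muscle and fibroblast list had a median of 0.76 (adjusted p = 0.0071, and adjusted p = 0.756 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Its most abundant members were the pericyte gene Rgs5, with a log2 fold change of 0.76 ± 0.22 (SE; 0.41 without KO replicate 1), and Pdgfra, with 0.20. The pericyte list also lost its call without KO replicate 1, where its median was 0.14 (adjusted p = 0.278), and without WT replicate 1, where it was 0.77 (adjusted p = 0.236), while without KO replicate 2 it was 1.22. The endothelial median was 1.06 without KO replicate 1, 1.02 without WT replicate 2 and 2.70 without WT replicate 1. Of the blood cell list only 3 members were tested, among them the globin gene Hba-a1 (log2 fold change 1.89) and Alas2 (1.21), and adjusted over the list alone all 3 passed. Without KO replicate 2 the blood cell list had 6 tested members and passed (adjusted p = 0.0249, and 0.816 with an estimated correlation).

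**Figure D2:**
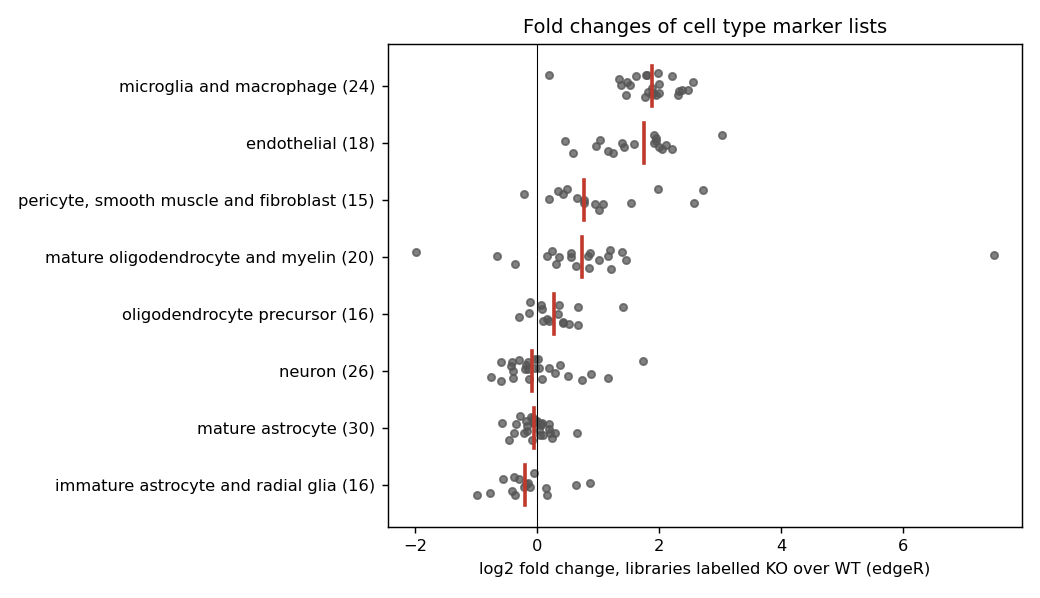
Log2 fold change between the libraries labelled KO and WT for each tested member (grey points, with random vertical scatter) of 8 cell type lists, with the list median as a red line and the number of members in brackets. The microglia and endothelial lists have medians of 1.88 and 1.75, the astrocyte and neuron lists medians between -0.20 and -0.05; the point at 7.48 is Trf, which had 0 counts in both WT libraries, so that its fitted value is no bound.

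Myelin genes were also higher as a group, beside the microglial rise of 1.88. In the list of mature oligodendrocytes and myelin, 17 of 20 tested members had a log2 fold change above 0, with a median of 0.73 (adjusted p = 0.0088, and adjusted p = 0.756 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. Mbp, which encodes myelin basic protein, had 414 ± 59 CPM in the libraries labelled KO and 230 ± 58 CPM in WT (SD, n = 2 each; log2 fold change 0.85 ± 0.21 SE, adjusted p = 0.37). Gpr17 had a log2 fold change of 0.35 ± 0.23 (SE), which was 0.06 without WT replicate 2 and 0.73 without WT replicate 1. The myelin list lost its call without WT replicate 2, where its median was 0.34 (adjusted p = 0.294), and its median was 1.27 without WT replicate 1. The oligodendrocyte precursor list, with a median of 0.27, did not pass (adjusted p = 0.079; 2 members passed adjusted over the list alone), and its most abundant members Olig1 and Cspg5 had log2 fold changes of 0.16 and 0.06. Its median was 0.67 without WT replicate 1 (adjusted p = 0.06) and 0.11 without WT replicate 2 (adjusted p = 0.407). That list passed over genes with a mean CPM of at least 5 (median 0.33, adjusted p = 0.0236, and 0.658 with an estimated correlation). The list of myelination signals secreted by astrocytes had a median of 0.16, which was -0.31 without KO replicate 1, and did not pass (adjusted p = 0.71). Its most abundant members were Tnc, at -0.42, and Ptn, at -0.20.

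Astrocyte genes did not pass as a group. The mature astrocyte list of 30 tested members had a median log2 fold change of -0.05 (adjusted p = 0.38), and 0 members passed over all genes or adjusted over the list alone. Slc1a3, the glutamate transporter of astrocytes, had 2825 ± 115 CPM in the libraries labelled KO and 2974 ± 31 CPM in WT (SD, n = 2 each), and Apoe had a log2 fold change of -0.01 ± 0.12 SE. The list of immature astrocytes and radial glia had a median of -0.20 (adjusted p = 0.053), with Fabp7 at -0.36 and Ptprz1 at -0.22, and adjusted over the list alone 1 member passed higher and 3 lower. Without KO replicate 1 that list passed (median -0.32, adjusted p = 0.0241, and 0.812 with an estimated correlation). The astrocyte morphogenesis list had a median of -0.07 (adjusted p = 0.71), and Sparcl1, its most abundant member beside Slc1a3, had a log2 fold change of -0.19. The astrocyte reactivity list had a median of 0.09 (adjusted p = 0.75), which was -0.11 without KO replicate 1 and 0.38 without KO replicate 2. Its members Gfap and Vim had log2 fold changes of 0.19 and -0.18. The synapse-promoting factors had a median of 0.08 (adjusted p = 0.74), with Nlgn3 at 0.11. The neuron list had a median of -0.09 and a mean of 0.04, and its test pointed down (adjusted p = 0.71; 1 member passed higher and 1 lower adjusted over the list alone), with Map2 at -0.20 and Dcx at -0.13. The ependymal and choroid plexus list, with 7 tested members, had no stable direction. Its median was 0.42 while its test pointed down (adjusted p = 0.99), and the median ran from -0.81 without KO replicate 1 (8 members) to 2.85 without WT replicate 2 (10 members). Foxj1 and Ccdc153 had log2 fold changes of -1.33 and -1.15, the former -0.65 without WT replicate 1.

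Immune and signalling lists were higher in the libraries labelled KO, in which the microglia list was also higher. The inflammatory cytokines and chemokines had a median log2 fold change of 1.88 (adjusted p = 7.5e-07, and adjusted p = 0.756 with an estimated correlation). Adjusted over the list alone 3 of its 19 members passed. Tgfb2 and Vcam1, the most abundant, had log2 fold changes of 0.17 and -0.10. Over genes with a mean CPM of at least 5 that list kept 10 members with a median of 0.40 (adjusted p = 0.0385), and without KO replicate 1 its median was 1.11. The interferon response had a median of 0.55 (adjusted p = 0.00044, and adjusted p = 0.756 with an estimated correlation). Its members Stat2 and Ifit2 had log2 fold changes of 0.86 ± 0.55 (SE) and -0.08, and that of Stat2 was 0.24 without WT replicate 2 and 1.99 without WT replicate 1. The extracellular matrix list had a median of 0.38 (adjusted p = 0.0088, and adjusted p = 0.756 with an estimated correlation), with Sparc at 0.87 (0.49 without KO replicate 1) and Tnc at -0.42. The MEK-ERK targets had a median of 0.24 (adjusted p = 0.021, and adjusted p = 0.756 with an estimated correlation). Fos and Jun had log2 fold changes of -0.56 ± 0.28 (SE) and -0.09, and that of Fos was -0.08 without WT replicate 2 and -0.92 without WT replicate 1. The list for protein folding stress had a median of 0.29 (adjusted p = 0.03, and adjusted p = 0.756 with an estimated correlation), with the chaperones Pdia3 at 0.32 and Canx at 0.28. Over all genes 0 members of these lists passed, and adjusted over the list alone 2 of the protein folding list and 0 of the interferon, matrix and MEK-ERK lists did. The protein folding list lost its call without any 1 of the libraries (adjusted p from 0.0675 to 0.182), and the MEK-ERK list without each library but KO replicate 2 (0.0716 to 0.19) and at a mean CPM of at least 5 (median 0.11, adjusted p = 0.172). The MEK-ERK median was 0.50 without WT replicate 1, and the interferon median 0.85. The matrix list lost its call without KO replicate 1, where its median was 0.07 (adjusted p = 0.25), and without WT replicate 2 (0.262), and its median was 0.83 without WT replicate 1.

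Genes of protein synthesis and respiration were slightly lower as groups in the libraries labelled KO, in which the microglia, endothelial and pericyte lists were higher (medians 1.88, 1.75 and 0.76). The cytosolic ribosomal proteins had a median log2 fold change of -0.21, with 40 of 50 members below 0 (adjusted p = 6.0e-04), and the nuclear genes of the mitochondrial respiratory chain had a median of -0.14, with 32 of 43 below 0 (adjusted p = 0.0088). Both had an adjusted p of 0.756 with an estimated correlation, and 0 members of either passed over all genes or adjusted over the list alone. Without WT replicate 2 neither list passed (medians -0.12 and -0.11, adjusted p = 0.163 and 0.154), without WT replicate 1 the ribosomal median was -0.33, and without KO replicate 2 the respiratory chain list did not pass (adjusted p = 0.174). Rpl4 and Rps2 had log2 fold changes of -0.14 and -0.52 ± 0.32 (SE). Rps2 has 11 near-identical copies, and its log2 fold change was -0.10 without KO replicate 2 and -1.10 without KO replicate 1. Atp5b and Sdha had log2 fold changes of -0.10 and 0.08. The lists for cell cycle (median -0.01, with Top2a at 0.15 and Rrm1 at -0.04), cholesterol synthesis (-0.03, with Hmgcs1 at -0.09 and Sqle at -0.02), glycolysis (0.11, with Eno1 at -0.20 and Pkm at 0.08), hypoxia (0.01, with Pgk1 at 0.05 and Ldha at 0.03), heat shock and dissociation (0.21, with Hspa8 at 0.19 and Hsp90aa1 at -0.12), apoptosis and p53 (0.04, with Sesn1 at 0.48 and Bcl2l1 at 0.20) and Sonic hedgehog, Wnt and Notch targets (-0.14, with a mean of 0.08, Notch1 at -0.17 and Hes5 at -0.11) did not pass; adjusted over the list alone 1 member of the glycolysis list and 2 of the apoptosis list passed. In all, 11 of 28 lists passed, 9 of them higher and 2 lower, 0 with an estimated correlation or with fry, and 5 without WT replicate 2.

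**Figure D3:**
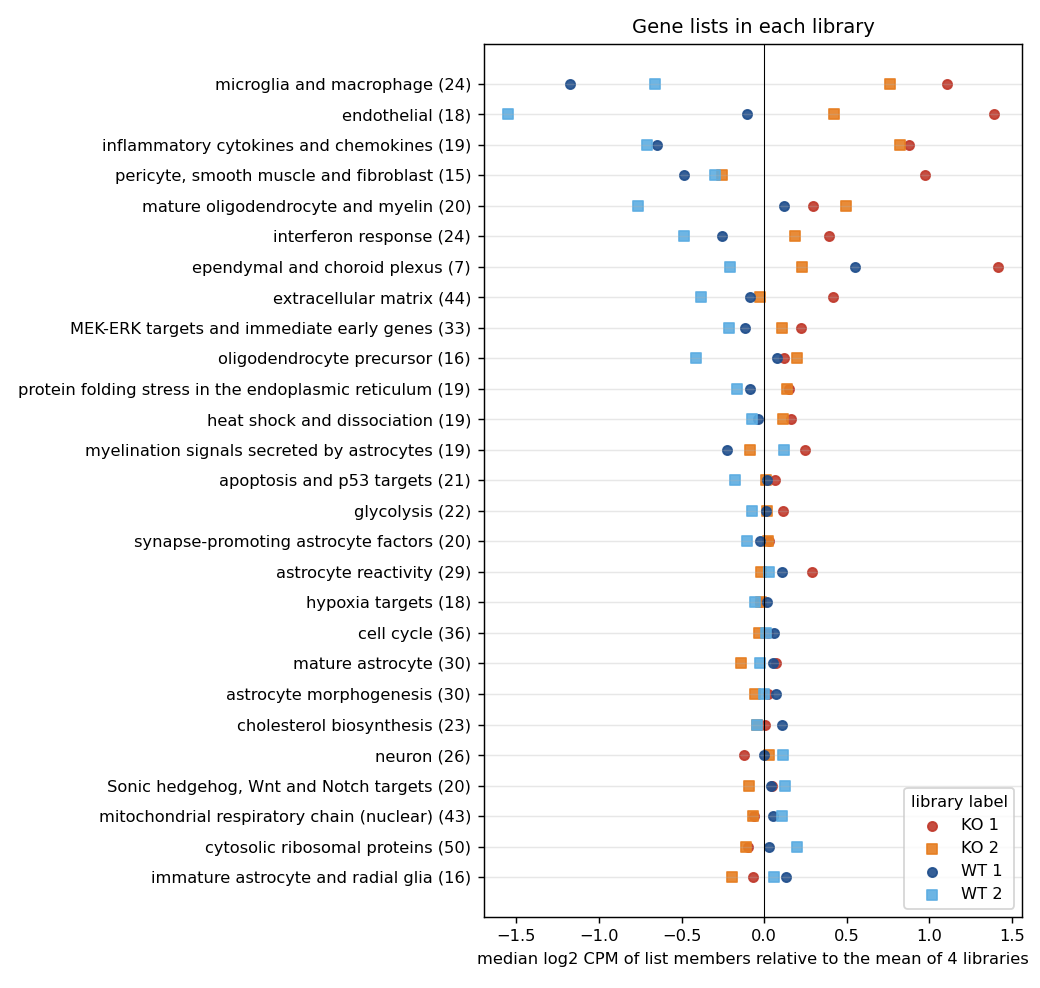
Median log2 CPM of the members of each gene list in each library, relative to the mean of the 4 libraries, for 27 of the 28 lists with at least 5 tested members (number in brackets). Both libraries labelled KO lie above both WT libraries for the microglia, endothelial and myelin lists, among others. WT replicate 2 lies lowest for the endothelial and myelin lists.

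The authors' deposited tables compare single libraries in 4 pairs. In them the authors called 6296, 6558, 6012 and 6321 genes significant, each a comparison of 2 libraries and not of the conditions. Of 18655 genes listed in all 4 of the authors' deposited tables, 960 were called higher in all 4, 287 were called lower in all 4, and 1103 were called in opposite directions by different tables. Over 17248 tested genes the fold change had 1 sign in all 4 pairs for 40.7%, against a mean of 33.3% in 100 simulations of unchanged libraries. At least 2-fold higher in all 4 pairs were 772 genes, against a mean of 304 and a highest value of 340 in the simulations, and at least 2-fold lower were 276, against a mean of 305. The pairs share libraries, so they are not independent. For the pairs KO 1 with WT 1 and KO 2 with WT 2, which share no library, 1251 genes were called higher in both of the authors' deposited tables and 453 lower, where independent lists of those lengths would share 415 and 147. Independent lists assume that each gene is equally likely to be called. Neither they nor the simulations, which drew each gene independently, allow for genes that move together, such as those of a cell type. The excess is thus no measure of an effect of the condition.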

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

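Alternatives with unlisted counts at their upper limit, no X and Y genes, a robust fit and no genes tracking microglia were chosen after the data were seen; the others were planned. The number of genes higher in the libraries labelled KO (3) and lower (0) moved to 315 and 63 with DESeq2, 25 and 3 with limma-voom, 52 and 4 with no low-count filter, 63 and 5 at a mean CPM of at least 5, and 14 and 1 at an adjusted p under 0.10. The causes were not tested. Leaving out 1 library gave from 0 (without KO replicate 2) to 41 (without WT replicate 2) higher and from 0 to 1 lower, each fit assuming that the lone library varies like the other group. Members of the fixed lists past the threshold (1) numbered 55 with DESeq2, 7 with limma-voom, 9 with no low-count filter, 9 at a mean CPM of at least 5, 5 at an adjusted p under 0.10, 2 with the robust fit, and from 0 to 12 leaving out 1 library. The other scalings, the upper limit of unlisted counts and the lists without X and Y genes gave 3 and 0. With the replicate number as a block 4 genes were higher and 0 lower, and 10 lists passed; same-numbered libraries did not deviate together (correlation 0.03 over genes), so the numbers do not pair them. P2ry12, Tpm3-rs7 and Eno1b lost their calls without KO replicate 2 (adjusted p = 0.067 each, with log2 fold changes of 2.68, 3.84 and 6.97), P2ry12 and Eno1b without WT replicate 1 (0.053 each, with 2.44 and 6.46), and Eno1b with limma-voom (0.11).

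Of the 11 lists past the list test, 0 passed with an estimated correlation and 0 with fry, and leaving out 1 library kept 7 (without KO replicate 1), 9 (without KO replicate 2), 8 (without WT replicate 1) and 5 (without WT replicate 2). With the lists that gained a call there, from 5 to 10 of 29 or 30 tested lists passed. The microglia, endothelial, interferon and inflammatory lists passed under each of the other alternatives chosen before the data were seen. The inflammatory median moved to 0.40 at a mean CPM of at least 5. The protein folding list lost its call with the block (adjusted p = 0.0866). At a mean CPM of at least 5 the MEK-ERK list lost its call (0.172) and the oligodendrocyte precursor list gained one (0.0236), and the immature astrocyte list gained one without KO replicate 1 (0.0241). The PD-1 pathway list, without KO replicate 1 (0.000523), and the blood cell list, without KO replicate 2 (0.0249), passed with more members tested than the 3 in all libraries. With an estimated correlation 0 lists passed at that CPM minimum or leaving out 1 library. The 502 genes tracking microglia all had a log2 fold change above 0, so leaving them out lowers the other lists by construction. Changes of direction occurred only in results that were not past the threshold. By list they were ependymal and choroid plexus (adjusted p = 0.963 with fry, 0.997 with RLE size factors, from 0.572 to 0.796 leaving out 1 library), astrocyte reactivity (0.913 at a mean CPM of at least 5, 0.846 without genes tracking microglia, 0.14 to 0.696), myelination signals (0.597 to 0.91), mature astrocyte (0.0586 to 0.742), astrocyte morphogenesis (0.406 to 0.902), Sonic hedgehog, Wnt and Notch targets (0.118 to 0.883), neuron (0.272 to 0.933), synapse-promoting factors (0.688 to 0.95) and hypoxia (0.742 to 0.95). By gene, the log2 fold changes leaving out 1 library ran from -0.18 to 0.15 for Apoe, -0.067 to 0.40 for Gfap, -0.40 to 0.0035 for Vim, -0.063 to 0.42 for Olig1, -0.013 to 0.14 for Cspg5, -0.16 to 0.0057 for Ifit2, -0.21 to 0.0093 for Vcam1, -0.12 to 0.045 for Rrm1, -0.029 to 0.26 for Nlgn3, -0.065 to 0.038 for Sqle, -0.018 to 0.11 for Pgk1, -0.065 to 0.12 for Ldha and -0.46 to 0.0026 for Actb. The alternative with a pseudocount was not run, since counts were at hand.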

Other observations

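The lists of macrophage and lymphocyte types, the tests of the microglial share and of neurons against microglia, and the window around Pdcd1 were chosen after the related results were seen, and so were the members named from those lists. Genes of macrophages of the brain's borders were higher in the libraries labelled KO, with a median log2 fold change of 2.22 over 9 tested members (camera over the added lists, adjusted p = 6.45e-05, and adjusted p = 0.215 with an estimated correlation). Over all genes 0 of the 9 passed. Stab1 and Mrc1, scavenger receptors of such cells, had log2 fold changes of 2.32 ± 0.27 and 2.48 ± 0.35 (SE; edgeR, adjusted p = 0.103 and 0.134). The median of the border macrophage list over the WT mean was 2.86 in KO replicate 1 and 1.925 in KO replicate 2. Its members lay higher in KO replicate 1 than in KO replicate 2 by a median of 1.64. In 7 of the 9 both libraries labelled KO lay above both WT libraries. Homeostatic microglial genes had a median of 1.98 over 14 members (adjusted p = 1.12e-11, and 0.21 with an estimated correlation), but 10 of the 14 are also in the fixed microglia list, and 1, P2ry12, passed over all genes. Genes of developmental white-matter microglia had a median of 0.61 over 15 members (adjusted p = 0.0083, and 0.215 with an estimated correlation), 2 of which are also in the fixed astrocyte lists, among them Apoe at -0.01. Relative to the mean of the libraries labelled KO, the list's median was -0.79 in WT replicate 1 and -0.16 in WT replicate 2, so it rests mainly on the former. Lgals3 and Fabp5 had log2 fold changes of -1.10 and -0.54, with both libraries labelled KO below both WT libraries. Spp1, a secreted phosphoprotein, had 486 and 969 CPM in the libraries labelled KO against 94.8 and 134 CPM in WT (adjusted p = 0.118). Of the B lymphocyte list 4 members were tested, with a median of 1.73 (adjusted p = 0.0068, and 0.21 with an estimated correlation). The immunoglobulin genes Ighm had 53.2 and 33.4 CPM in the libraries labelled KO against 4.68 and 6.74 CPM in WT, and Ighd 10.9 and 10.5 CPM against 0 in both. Cd79b and Cd22 had log2 fold changes of 0.54 and -1.54. Over all genes 0 members of the white-matter and B lymphocyte lists passed. Of the T lymphocyte list and of the neutrophil and monocyte list 1 member each was tested. These list tests used a minimum of 3 tested members, chosen with the lists, where the fixed lists needed 5; under that minimum of 5 the B lymphocyte list would have had no test.

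Among 2675 terms of the deposited gene annotation, 79 were higher and 2 lower at an adjusted p under 0.05 by camera with the preset correlation, and 0 with an estimated one (smallest adjusted p = 0.997). At 2 residual degrees of freedom a term could hardly pass the latter over so many terms. The first were chemokine-mediated signaling (20 genes, median log2 fold change 1.99, adjusted p = 1.94e-07) and the immune response (88 genes, 0.65, adjusted p = 7.03e-07). The microglia list was itself higher (median 1.88). Cytoplasmic translation (160 genes, -0.23, adjusted p = 0.0018) and translation (264 genes, -0.19, adjusted p = 0.018) were the lower ones.

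Microglial and endothelial transcripts were higher in the libraries labelled KO while the mature astrocyte list had a median of -0.05 and the immature astrocyte list, with 12 of 16 members below 0, one of -0.20, and neither passed. A loss of purity that raised all other cell types alike would raise neuronal transcripts too. The upper quartile of the neuron list, 0.269, lay below the lower quartile of the microglia list, 1.60, which argues against that form only. A loss of purity that spared neurons stays open, since the test cannot see it. The criterion was also set after the list values were seen. A larger share of microglia in the libraries labelled KO may account for the microglial part. Of the list, 95.8% (23 of 24 members) lay within 1 log2 unit of its median of 1.88, with an SD of 0.49. That range is wide and was set after the values were seen, so it does not establish a common fold. The list of developmental white-matter microglia, with a median of 0.61 and an SD of 1.39, did not move by that fold. It shares 2 of its 15 members with the fixed astrocyte lists, among them Apoe, at 3488 CPM in WT. A larger share of microglia need not raise such genes by that fold, so the comparison decides nothing about the share. Whether such a share would come from the isolation or from the animals was not tested, and an effect of the PD-1 deletion itself stays open. Without KO replicate 2, the male library, the microglia list still had a median of 2.01.

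Near-identical gene copies made up 2 of the 3 genes past the threshold. Over 577 copies at 95% identity or more, the median log2 fold change was -0.0962, which argues against a difference in mapping or read length that would move copies alike. Of the 10 copies with an unadjusted p under 0.01, 9 (90%) had a parent that moved the other way, against 209 of 567 other copies (36.9%; Fisher's exact test, two-sided, p = 0.000945). Tpm3-rs7 and Eno1b, which prompted the test, are among the 10 and among the 9, and it was not repeated without them. All 10 were higher in the libraries labelled KO, while the other copies moved in either direction. The comparison was not matched for direction, so its p-value does not isolate an exchange of reads. Examples were Tpm3-rs7 at 3.83 with Tpm3 at -0.46, Rps3a2 at 2.67 with Rps3a1 at -0.83, and Gm8822 at 3.31 with Actr3 at -0.71. Reads moving between copy and parent at single loci, as a sequence difference between the groups' animals could bring about, are a candidate explanation, and the strains were not compared here.

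Stk25 and D2hgdh, among the leading lower genes, lie beside Pdcd1 on chromosome 1, and the window around Pdcd1 was tested because of them. Of 34 genes within 3 Mb, 5 had an unadjusted p under 0.01 (14.7%, against 2.81% of 12690 genes), but that count includes the pair that prompted it. Without them 3 of 32 genes did (9.38%), and 93.8% of 11990 overlapping windows of 32 neighbouring genes elsewhere held fewer, below the 95% set for the test, so a difference in DNA around the targeted locus between the groups' animals stays open. The WT mice carried a floxed PD-1 gene. If the deletion was made from the same floxed allele, both groups would share the DNA around it, which was not tested. Of the 5 genes 2, Traf3ip1 and Neu4 (log2 fold changes 1.72 and 1.41), track the microglia list, short of the 50% set before. A gene picked by a low p and higher in the libraries labelled KO will tend to track that list, so the test decides nothing for the higher genes. For those, genes that follow the microglia cannot be told apart from the other explanations. Neu4 is also a member of the fixed oligodendrocyte precursor list, which had 13 of 16 members above 0 and did not pass. Stk25 and D2hgdh were lower, at -1.70 and -2.97, while all 502 genes tracking the microglia list lay above 0. Following that list thus does not cover this pair. An effect of the deletion on its neighbours was not tested.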
